A study of Homo sapiens with 8 samples.

How the data were processed

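The series holds 8 arrays of primary human dermal fibroblasts: irradiated and sham cells at 1 and 5 days of recovery, 2 arrays in each of 4 groups. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and purified on a column, and single-stranded cDNA made from amplified cRNA was fragmented and labelled with biotin. The design text names an exon array, while the annotation table matches the probe set numbers of the values to another array of the same maker, so the array type is not settled; the gene symbols used here come from that table.

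The deposited table holds log2 values, 1 per probe set and array. The log base and the normalization between arrays are not given in the sources used here, nor is the software. In all 28829 probe sets the 2 sham values of a recovery time in the deposited values sum to 0 within 1e-06, so the authors' values are relative to the mean of the 2 sham arrays of that time. Base 2, the usual base for such arrays, was assumed. The numeric spacing is compatible with it: every deposited value over 0.001 in size was a multiple of 1 divided by 2 to the power of 21 (tolerance 0.01 steps), as differences of single-precision numbers between 4 and 16 are, which is a range that log2 array signals take and too high for log10. Natural logarithms are not excluded by the spacing, so the log2 unit and every fold printed rest on this assumption. For 9711 probe sets (33.7%) all values were multiples of 1 divided by 2 to the power of 20, which places their signals at 8 or above. Beyond this class no absolute signal can be read from centred values, and none is reported. Array medians lay between -0.0381 and 0.0381.

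Of the probe sets, 19291 had exactly 1 gene symbol, 1735 several and 7803 none in the annotation table; 19260 of the first kind had a gene number found in the current gene table. Only the first kind was used, as 18372 genes, of which 682 had over 1 probe set. The design had set the row with the highest mean as the value of a gene. The mean of centred values is not a brightness and would pick rows by the outcome, so the mean of all rows of a gene was used, and the written rule was run as an alternative. The choice was exchanged after the values were seen.

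A limma model with 1 mean per group was fitted to all 8 arrays (4 residual degrees of freedom), with empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes of a contrast, at an adjusted p under 0.05. The 3 contrasts were irradiated minus sham at 1 day, the same at 5 days, and their difference. The planned comparison of sham cells at 5 days with sham cells at 1 day was not made, because centring fixes it at 0. A fit of only the 4 arrays of a recovery time (2 residual degrees of freedom) was set as an alternative before the data were examined, and the text names the fit wherever it matters. Standard errors are those of the fit of 8 arrays. Gene lists (29, fixed before the data were examined, with 673 genes of which 627 were measured, 1 by its older symbol) were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists, and with an estimated correlation, on ranks and with fry. With an estimated correlation camera also uses the few residual degrees of freedom of the fit, so a lost call does not by itself show shared noise. fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Counts of members are given over all genes and adjusted over the list alone.

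Genes were named by a rule set before the data were examined: for each contrast, genes past the threshold whose arrays do not overlap (up to 10 per direction, 5 for the difference), filled to 5 per direction by smallest p; MMP1, MMP3 and any other MMP or TIMP; up to 4 members of each list spoken of, by smallest p; and members of marker lists of other cell types that pass. Names outside this rule were chosen after their values were seen and are in the closing part.

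The alternatives set before the data were examined were subtraction of each array's median, a variance trend with robust moderation, the groups compared alone, the replicate number as a block, a fold of at least 1.5, each array of the groups compared left out in turn, and for lists the estimated correlation, ranks and fry. With an array left out, the lone array of a group is assumed to vary like the other groups. Most alternatives for lists keep the preset correlation, so a count of alternatives passed repeats that assumption and is not separate support. For a contrast within a recovery time, leaving out either array of a group at the other time gives an identical fit. Such alternatives repeat each other in the counts of alternatives passed, for genes and for lists. A planned filter on dim genes and quantile normalization were not run, since the mean of centred values does not rank genes by brightness and centring leaves no common distribution. The variance trend was run, but it is fitted on this same mean, which the irradiated arrays alone set. It therefore does not model signal level. The numeric spacing gives only a coarse class, signals of at least 8 or not, which took the place of the filter. Array weights, genes with signals of at least 8, all probe sets tested, a crossed pairing, the row with the highest mean as an alternative, the 4 arrays with an estimated correlation and leaving out arrays of the other recovery time were added, and further genes run through the alternatives, after the data were seen. Replicates carry the same numbers in each group. Over the 6 pairs of groups, the correlation across genes of the differences between replicate 1 and 2 ran from -0.616 to 0.372, so the numbers were not taken to pair samples.

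The tests were run on simulated data with the spread of each gene over all groups, scaled to the overall spread of each group, and again with an equal spread in all groups, with 100 genes changed by 1 log2 unit and 100 by 0.5, among 18372 genes. Genes were drawn independently of each other, so noise shared between genes was left out. The false calls below are therefore not an error rate for the real arrays. For the comparison at 1 day, the fit of 8 arrays recovered 89% and 47% with 0 false calls, and the fit of 4 arrays 98% and 66% with 6 false calls. With an equal spread the order was the other way, 84% and 37% with 5 false calls for 8 arrays and 60% and 0% with 4 for 4 arrays. At 5 days with the spread of each group the fit of 8 arrays recovered 87% and 65% with 111 false calls and the fit of 4 arrays 0%, against 84% and 45% with 6 false calls and 53% and 0% with 1 for an equal spread. With array weights and the spread of each group, the fit of 8 arrays recovered 98% and 89% with 10 false calls at 1 day. At 5 days it recovered 71% and 28% with 4 false calls. For an equal spread it recovered 84% and 37% with 5 false calls at 1 day and 84% and 47% with 7 at 5 days. R 4.3.3 and limma 3.58.1 were used.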

Results

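Primary human dermal fibroblasts, the cells that make and remodel the collagen matrix of the skin, were exposed in culture to a single dose of 12 J/cm2 of simulated sunlight made up mostly of UVA with some UVB. Sham cells received 0 J/cm2. RNA was collected after 1 day or 5 days of recovery and measured on whole-transcript gene expression arrays, giving 8 arrays in 4 groups of 2. The labels number the arrays of a group 1 and 2 and do not say whether they came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The deposited values are log signals, taken to be of base 2, relative to the mean of the 2 sham arrays of the same recovery time, so each change below is irradiated minus sham at that time, with n = 2 arrays per group. The number of arrays limits the precision. The spread between replicates over 18372 genes was 0.068 on the log2 scale (replicate SD, n = 2) for irradiated cells and 0.087 for sham cells at 1 day, against 0.12 for irradiated cells and 0.24 for sham cells at 5 days.

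**Figure D1:**
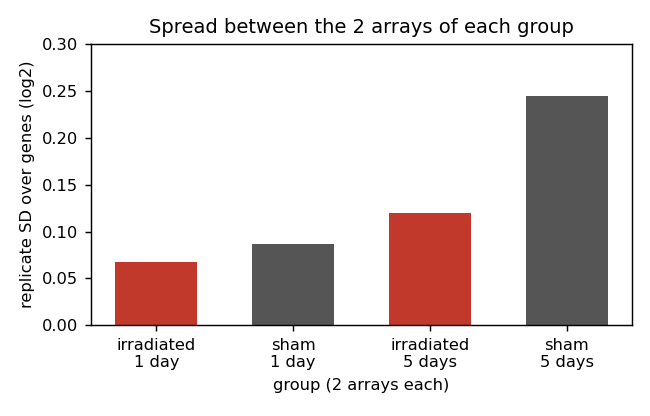
Bars give the SD between the 2 arrays of each group over all genes on the log2 scale, for irradiated and sham cells at 1 and 5 days. The bar of the sham cells at 5 days (0.24) is the highest, and that of the irradiated cells at 1 day (0.068) the lowest.

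The series title names MMP1 and MMP3, and the first comparison asked which genes differed between irradiated and sham cells 1 day after exposure. MMP3 (stromelysin-1, which degrades proteoglycans, fibronectin and other matrix proteins) rose by a log2 change of 1.26 (SE 0.085; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0256 in the fit of all 8 arrays). Over 16 alternatives its adjusted p ran from 1.39e-04 to 0.969, and 8 passed. MMP3 was the only gene called, and this call ended, with 0 genes called, without irradiated replicate 1 or 2 at 1 day, sham replicate 1 or 2 at 1 day, or irradiated replicate 1 or 2 at 5 days, while 118 genes passed without either sham array at 5 days. The call of MMP3 also ended with the replicate number as a block and with a variance trend. In centred values this trend is fitted on the mean of the irradiated arrays and not on signal, so it is not a sound check. The highest adjusted p of MMP3 above came from this trend. MMP1 (interstitial collagenase) stood at 1.53-fold, a log2 change of 0.62 (SE 0.071). Its adjusted p was 0.0777 over all genes in the fit of 8 arrays, and it rose in the fit of the 4 arrays at 1 day alone (adjusted p = 0.0277), with a range of 0.00274 to 1 over 16 alternatives, of which 5 passed. MMP14, the membrane-bound collagenase that activates pro-MMP2, and MMP2 (gelatinase A) rose in the fit of 4 arrays as well, with log2 changes of 0.61 (SE 0.10, adjusted p = 0.0277) and 0.40 (SE 0.068, adjusted p = 0.0358). Of the 19 measured matrix metalloproteinases, 17 lay above 0 and 2 below, with a median log2 change of 0.10 (0.51 among the 6 members with signals of at least 8). Adjusted over the list alone, 4 members (MMP1, MMP2, MMP3 and MMP14) passed and 15 did not. The list as a whole lay higher than other genes (camera with a preset correlation, adjusted p = 1.33e-08), with adjusted p = 0.256 with an estimated correlation. Because the study is about MMP1 and MMP3, their direction is not independent evidence for the list.

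Other family members did not pass at 1 day. MMP12 and MMP19 had log2 changes of 0.15 (SE 0.063) and 0.18 (SE 0.064). MMP16 had a value as large as that of MMP14, 0.61, with an SE of 0.45. This SE is pooled over the arrays of both recovery times, so it does not give the spread at 1 day alone. In the limma fit of the arrays at 1 day alone, MMP16 had adjusted p = 0.169, against 0.153 for MMP19 and 0.171 for MMP12. The remaining members, MMP7, MMP8, MMP9, MMP10, MMP11, MMP13, MMP15, MMP17, MMP24, MMP25, MMP27 and MMP28, lay between -0.040 (MMP27) and 0.14 (MMP15), and MMP7, MMP8, MMP9, MMP13, MMP24 and MMP27 changed sign when 1 array at 1 day was left out. Among 9 measured inhibitors of matrix proteases, TIMP3 had a log2 change of -0.26 (SE 0.069) and passed only when adjusted over the list alone (adjusted p = 0.033, against 0.418 over all genes). TFPI2, a secreted serine protease inhibitor, had 0.76 (SE 0.12; adjusted p = 0.00327 over the list alone, 0.151 over all genes). TIMP1, TIMP2 and TIMP4 had log2 changes of 0.040, 0.070 and -0.085. The list itself did not pass (median -0.050, mean 0.022, adjusted p = 0.907).

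**Figure D2:**
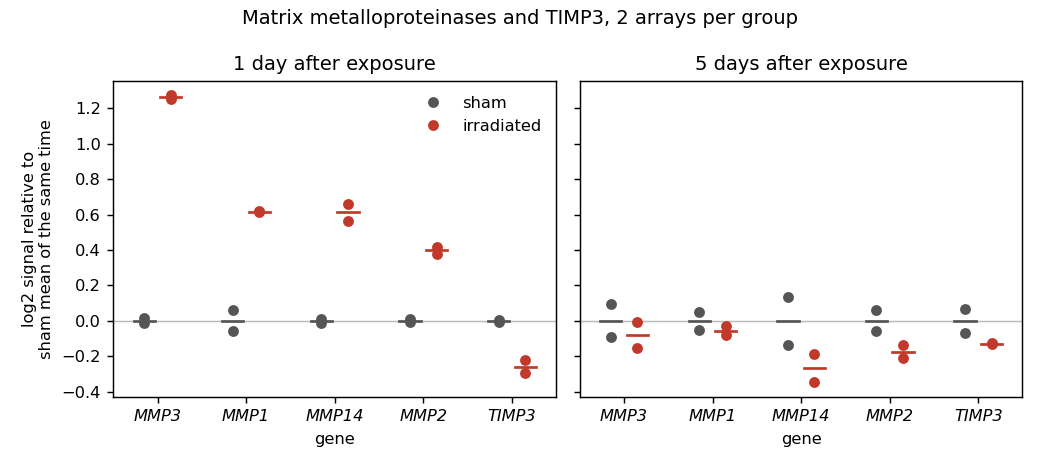
Points give each array's log2 signal relative to the sham mean of the same recovery time for MMP3, MMP1, MMP14, MMP2 and TIMP3, and short lines give the group means of 2 arrays. At 1 day the irradiated arrays lie above the sham arrays for the 4 metalloproteinases (mean log2 changes of 1.26, 0.62, 0.61 and 0.40), and at 5 days the mean changes of MMP3 and MMP1 are -0.078 and -0.055.

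The fit of all 8 arrays called no gene besides MMP3 at 1 day. The fit of the 4 arrays called 165 (37 higher, 128 lower in irradiated cells), MMP1, MMP2, MMP3 and MMP14 among the higher. The genes named next all passed in the fit of 4 arrays. GPNMB, a glycoprotein of lysosomal and melanosomal membranes, rose 1.44-fold (log2 change 0.53, SE 0.061, adjusted p = 0.0277). The amino acid transporter SLC7A8 rose 1.81-fold (adjusted p = 0.0216) and the integrin beta-3 gene ITGB3 rose 1.63-fold (adjusted p = 0.0302). EDN1, which encodes the vasoconstrictor endothelin-1, was 1.82-fold lower (log2 change -0.87, SE 0.088, adjusted p = 0.0216), and PTGIS, the prostacyclin synthase, was 1.84-fold lower (adjusted p = 0.0247). TMEM45A, the matrix gene CCDC80 and the carboxypeptidase gene CPA4 were 1.61-fold, 1.58-fold and 1.56-fold lower (adjusted p = 0.0216 each). In the fit of 8 arrays the adjusted p of these 8 genes lay between 0.0777 and 0.109. The counts moved with all probe sets tested, a setting that also changes the averaging of probe sets and the moderation. With all 28829 probe sets tested, the fit of 8 arrays called 0 (lowest adjusted p = 0.0585; 1864 at an unadjusted p under 0.05) and the fit of 4 arrays called 1. Over the 18372 genes, 1240 had an unadjusted p under 0.05 in the fit of 8 arrays, 444 higher and 796 lower. This number was 631 and 591 without irradiated replicate 1 and 2 at 1 day, 657 and 677 without sham replicate 1 and 2 at 1 day, and 2478 without either sham array at 5 days. With each array's median subtracted 14 genes passed (4 higher, 10 lower).

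Genes of the cell cycle lay lower in irradiated cells at 1 day. Of 35 measured DNA replication genes, 34 lay below 0, with a median log2 change of -0.31. Adjusted over the list alone, 21 members passed, all of them lower; adjusted over all genes, 0 passed in the fit of 8 arrays and 11 fell in the fit of 4 arrays. MCM4, a subunit of the replicative helicase, fell by 0.43 on the log2 scale (SE 0.074, adjusted p = 0.0296 in the fit of 4 arrays), and GINS2 and GINS4 of the same helicase complex fell by 0.49 and 0.38 (adjusted p = 0.0277 and 0.0428). MCM6 had -0.34 (adjusted p = 0.051). Of 35 mitotic genes, 31 lay below 0 (median -0.23), 7 passed adjusted over the list alone, all lower, and 4 fell in the fit of 4 arrays. Among them were the mitotic kinesin KIF20A (log2 change -0.62, SE 0.10, adjusted p = 0.0284) and the phosphatase CDC25C, which activates CDK1 (-0.53, SE 0.095, adjusted p = 0.0333). BUB1 and CCNB2 had -0.41 and -0.36. Of 30 replication-dependent histone genes, 28 lay below 0 (median -0.16), and 0 passed adjusted over the list alone or over all genes. H4C9, H1-1, H3C1 and H2AC8 had log2 changes of -0.29, -0.30, -0.31 and -0.18. By camera the adjusted p was 3.99e-25 for replication genes, 4.20e-12 for mitotic genes and 9.47e-10 for histone genes with the preset correlation. These calls were lost with an estimated correlation: adjusted p = 0.256 with an estimated correlation for replication genes, 0.256 for mitotic genes and 0.529 for histone genes.

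Targets of the damage-responsive transcription factor p53 lay higher. Of 33 measured members, 25 lay above 0 (median log2 change 0.093), and 5 passed adjusted over the list alone, all higher. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 1.46-fold (log2 change 0.55, SE 0.086, adjusted p = 0.0277 in the fit of 4 arrays), and the stress cytokine GDF15 rose 1.41-fold (adjusted p = 0.0284). SESN1 and SPATA18 had log2 changes of 0.33 and 0.32 and passed over the list alone only (adjusted p = 0.0337 each). The list's adjusted p was 2.79e-06, and adjusted p = 0.3 with an estimated correlation. Of 25 lysosome and autophagy genes, 23 lay above 0 (median 0.092, adjusted p = 3.46e-07, and 0.389 with an estimated correlation), and 3 passed adjusted over the list alone. The median was 0.14 among the 20 members with signals of at least 8 and 0.16 without sham replicate 2 at 1 day. NPC1, which exports cholesterol from lysosomes, and the protease CTSD rose in the fit of 4 arrays, by log2 changes of 0.37 (SE 0.073) and 0.34 (SE 0.072). CTSK, a collagen-degrading protease, and NPC2 had 0.33 and 0.23. Of 19 fibrillar and basement membrane collagens, 15 lay above 0 (median 0.082, adjusted p = 0.00676, and 0.422 with an estimated correlation), and 0 passed adjusted over the list alone. COL6A3, COL4A1 and COL7A1 had log2 changes of 0.18, 0.24 and 0.19, and COL12A1 had -0.17. The fibrillar collagen genes lay near 0 on both sides. COL1A1, COL3A1 and COL11A1 had -0.0425, -0.0379 and -0.057. COL1A2, COL5A1, COL5A2 and COL5A3 had 0.081, 0.038, 0.064 and 0.033. The call of the collagens ended without sham replicate 2 at 1 day (median 0.045, adjusted p = 0.0958).

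All 24 measured hypoxia and glycolysis genes lay below 0 at 1 day, with a median log2 change of -0.20 (adjusted p = 4.98e-16, and 0.256 with an estimated correlation). Adjusted over the list alone 7 passed, and 5 fell in the fit of 4 arrays. PFKFB4, a regulator of glycolytic flux, was 1.71-fold lower (log2 change -0.77, SE 0.086, adjusted p = 0.0216), NDRG1 fell by 0.45 on the log2 scale, the glucose transporter SLC2A1 by 0.41, and KDM3A, a histone H3 lysine 9 demethylase, by 0.38 (adjusted p = 0.0296, 0.0358 and 0.0358). Of 26 genes of the unfolded protein and integrated stress responses, 22 lay below 0 (median -0.13, adjusted p = 1.25e-05, and 0.529 with an estimated correlation), and 4 lower and 1 higher passed adjusted over the list alone. The 4 that fell in the fit of 4 arrays, VLDLR, DDIT4, ASNS and PSAT1 (log2 changes of -0.59, -0.60, -0.49 and -0.46), encode a lipoprotein receptor, an mTORC1 inhibitor and synthetic enzymes of asparagine and serine, and none is an endoplasmic reticulum chaperone. Of 35 secreted inflammatory and senescence-associated factors, 21 lay below 0 (median -0.025, mean -0.096, adjusted p = 0.0103, and 0.256 with an estimated correlation), and adjusted over the list alone 7 passed lower and 2 higher. Camera on ranks ended this call (adjusted p = 0.259). The median of the list was -0.055 and -0.044 without irradiated replicate 1 and 2 at 1 day, -0.0076 and -0.060 without sham replicate 1 and 2 at 1 day, and -0.22 among the 16 members with signals of at least 8. The chemokine genes CCL2 and CXCL12, the adhesion gene ICAM1 and IGFBP3, which binds insulin-like growth factors, fell in the fit of 4 arrays, with log2 changes of -0.61, -0.50, -0.48 and -0.88 (adjusted p = 0.0284, 0.038, 0.0296 and 0.0216). IL33 and EREG of the same list lay higher, with log2 changes of 0.52 and 0.44. Of the 18 alternatives run for each list called at 1 day, 14 to 16 passed, and the adjusted p over these lists ran from 1.37e-26 to 0.529.

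The other lists fixed before the data were examined did not pass at 1 day. For the 41 histone H3 methyltransferases and demethylases the median log2 change was 0.0092 (adjusted p = 0.422), with mean and test on the lower side. Medians and adjusted p were -0.032 and 0.907 for NRF2 antioxidant genes, -0.055 and 0.143 for other antioxidant enzymes, 0.014 and 0.663 for metallothioneins, 0.017 and 0.693 for immediate early genes, and 0.0024 and 0.907 for interferon-stimulated genes. They were 0.024 and 0.548 for TGF-beta response genes, -0.045 and 0.0967 for nucleotide excision repair, 0.040 and 0.136 for cholesterol synthesis, and -0.043 and 0.541 for heat shock genes. They were 0.027 and 0.71 for collagen processing, where mean and test lay below 0, -0.0026 and 0.86 for elastic fibres, proteoglycans and hyaluronan, and 0.073 and 0.0613 for dermal fibroblast identity genes. Adjusted over the list alone, 4 lower and 1 higher members of the elastic fibre list passed. Marker lists of other skin cell types did not pass either (keratinocyte 0.011 and 0.548, melanocyte -0.043 and 0.474, endothelial 0.056 and 0.143, leukocyte and macrophage 0.047 and 0.335, pericyte and smooth muscle 0.023 and 0.907). Single markers that passed adjusted over the list alone were KDR, higher (log2 change 0.55, adjusted p = 0.0127), and SRGN, lower (-0.54, adjusted p = 8.25e-04).

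At 5 days MMP1 and MMP3 had log2 changes of -0.055 (SE 0.071, adjusted p = 0.774) and -0.078 (SE 0.085, adjusted p = 0.73), MMP3 with the opposite sign (0.016) without sham replicate 1, and the question was which genes still differed from sham cells. No gene passed: limma called 0 of 18372 genes in the fit of 8 arrays (1120 at an unadjusted p under 0.05, 166 higher and 954 lower) and 0 in the fit of the 4 arrays at 5 days (207). Without sham replicate 1 at 5 days the balance turned, with 1195 at an unadjusted p under 0.05, 766 higher and 429 lower. The number was 6963 without sham replicate 2 at 5 days, 304 without irradiated replicate 1 at 5 days, 583 without either irradiated array at 1 day and 648 without either sham array at 1 day. MMP14 and MMP2 had log2 changes of -0.27 (SE 0.10) and -0.17 (SE 0.068). The largest value of the other metalloproteinases was 0.42 (SE 0.45) for MMP16, and TIMP1, TIMP2, TIMP3 and TIMP4 had 0.0069, -0.15, -0.13 and -0.24. The genes with the smallest p were CC2D2B, RPEL1, PM20D1-AS1, TTC24 and ZNF367, with log2 changes of 0.41, 0.46, 0.25, 0.26 and 0.30, and ZNF587, BIVM, CEMIP (which takes part in hyaluronan breakdown), ZNF799 and the matrix proteoglycan gene PRELP, with -0.40, -0.51, -0.42, -0.44 and -0.30 (adjusted p = 0.636 each). PRELP passed when adjusted over the list alone (adjusted p = 0.0302). Its log2 change at 1 day was -0.30 as well. The 2 sham arrays at 5 days differed from each other by over 1 log2 unit for 544 genes. Without sham replicate 2 at 5 days, 3795 genes passed (1773 higher, 2022 lower), of which 2048 had the same sign and 159 the same sign and an unadjusted p under 0.05 without sham replicate 1, when 0 passed.

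Among gene lists at 5 days, 6 passed camera with the preset correlation, and 0 with an estimated correlation (adjusted p = 0.797 for each of the 6 with an estimated correlation). Of 25 lysosome and autophagy genes, 23 lay below 0 (median log2 change -0.17, adjusted p = 2.52e-05). HEXA, NEU1, NPC1 and BECN1 had -0.37, -0.34, -0.25 and -0.22. Of 19 collagen processing genes, 17 lay below 0 (median -0.12, adjusted p = 0.0193), among them P4HA2, LOXL4, P3H1 and LOXL3 with -0.25, -0.30, -0.22 and -0.25. Of 25 genes of elastic fibres, proteoglycans and hyaluronan, 19 lay below 0 (median -0.12, adjusted p = 0.0265), among them MFAP4, TNC and FBLN1 with -0.28, -0.16 and -0.17. Of 35 secreted inflammatory factors, 25 lay below 0 (median -0.10, adjusted p = 0.0193), among them CXCL12, IGFBP5, ICAM1 and NFKBIA with -0.32, -0.29, -0.33 and -0.32. Of 24 hypoxia and glycolysis genes, 19 lay below 0 (median -0.089, adjusted p = 0.0193), among them PFKFB4, ALDOC, SLC2A3 and ADM with -0.27, -0.32, -0.24 and -0.18. Of 35 mitotic genes, 20 lay above 0 (median 0.065, adjusted p = 0.0193, and 0.0907 with each array's median subtracted), among them MAD2L1, MKI67, ANLN and CENPE with 0.41 (SE 0.18), 0.22 (SE 0.10), 0.50 (SE 0.27) and 0.70 (SE 0.38). Adjusted over the list alone, 0 members of 5 of these lists passed and 1 of the elastic fibre list (PRELP).

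The 5-day lists depended on single arrays of that time. Without irradiated replicate 2, the mitotic list had a median of 0.014 (adjusted p = 0.139), secreted factors -0.11 (adjusted p = 0.0638) and hypoxia genes -0.15 (adjusted p = 0.0373). Without irradiated replicate 1, elastic fibre genes had -0.081 (adjusted p = 0.0522) and mitotic genes 0.11 (adjusted p = 0.0045). Without sham replicate 2, 2 lists passed (lysosome genes with a median of -0.27 and adjusted p = 0.0167, and mitotic genes with 0.00114). Collagen processing then had -0.22 (adjusted p = 0.174), elastic fibres -0.19 (0.387), secreted factors -0.11 (0.608) and hypoxia genes -0.17 (0.121). Without sham replicate 1, the mitotic list had a median of 0.014 (adjusted p = 0.736) and the hypoxia list -0.048 (adjusted p = 0.106), while the lysosome list had -0.092 (adjusted p = 1.04e-04), collagen processing -0.059 (0.0443) and elastic fibres -0.061 (0.0235). Among members with signals of at least 8, the lysosome and mitotic lists passed and the other 4 did not (adjusted p between 0.359 and 0.482). Over 18 alternatives the adjusted p of the lysosome list ran from 1.96e-06 to 0.876 and 15 passed, against 12 or 13 for the other 5 lists. The other lists did not pass at 5 days. Medians and adjusted p were -0.063 and 0.181 for DNA replication genes, -0.011 and 0.86 for histone genes, -0.078 and 0.275 for p53 targets, 0.0028 and 0.981 for matrix metalloproteinases, -0.074 and 0.275 for collagens, -0.13 and 0.0624 for inhibitors of matrix proteases, and -0.13 and 0.0624 for the unfolded protein and integrated stress responses. They were -0.078 and 0.0863 for NRF2 antioxidant genes, -0.089 and 0.0863 for other antioxidant enzymes, -0.036 and 0.642 for metallothioneins, -0.080 and 0.161 for immediate early genes, 0.024 and 0.393 for interferon-stimulated genes, and -0.080 and 0.161 for TGF-beta response genes. They were -0.10 and 0.161 for nucleotide excision repair, -0.14 and 0.0727 for cholesterol synthesis, -0.043 and 0.85 for heat shock genes, where the mean was 0.040, -0.064 and 0.275 for histone H3 methyltransferases and demethylases, and -0.080 and 0.926 for dermal fibroblast identity genes, where the mean was 0.014. Marker lists of other cell types did not pass (keratinocyte 0.049 and 0.196, melanocyte -0.0019 and 0.596, endothelial 0.026 and 0.502, leukocyte and macrophage 0.018 and 0.374, pericyte and smooth muscle -0.082 and 0.469).

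**Figure D3:**
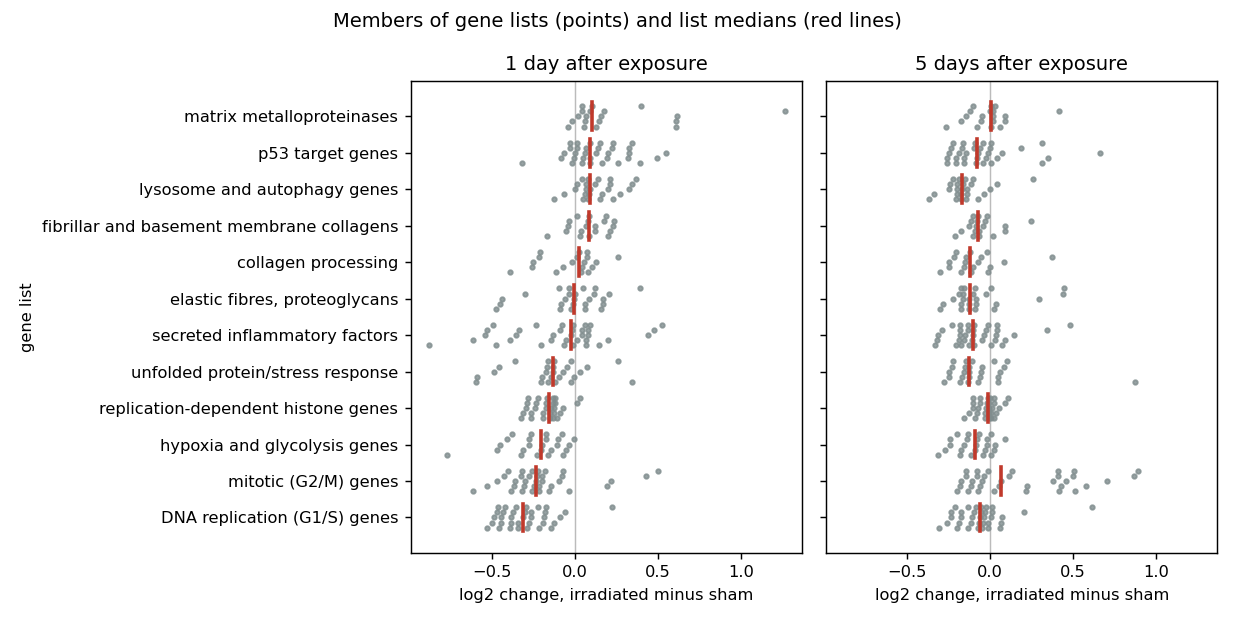
Each point is a member of a gene list, placed by its log2 change (irradiated minus sham, 2 arrays per group) at 1 day or 5 days, and red lines mark list medians. DNA replication genes have a median of -0.31 at 1 day and -0.063 at 5 days, and lysosome and autophagy genes 0.092 and -0.17.

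The change of the irradiation effect between the recovery times was tested as 5 days minus 1 day. MMP3 had the smallest p, with a difference of -1.34 on the log2 scale (SE 0.12, adjusted p = 0.179 over all genes), and MMP1 had -0.67 (SE 0.10, adjusted p = 0.697). Adjusted over the list alone, the differences of MMP3, MMP1, MMP14 and MMP2 passed (adjusted p = 1.85e-04, 0.00261, 0.00261 and 0.00261), and that of MMP19 had adjusted p = 0.0371. GPNMB and ITGB3 had differences of -0.72 and -0.95 and the small nucleolar RNA gene SNORD116-21 had -0.65, while ZNF367, CCDC80, SRGN, TMEM45A and EDN1 had 0.73, 0.62, 0.61, 0.57 and 0.73 (adjusted p between 0.644 and 0.697). Over all 18372 genes limma called 0 (885 at an unadjusted p under 0.05, 318 higher and 567 lower at 5 days). Without sham replicate 1 at 5 days the balance turned, with 1502 at an unadjusted p under 0.05, 885 higher and 617 lower, and 0 called. This number was 566 without irradiated replicate 1 at 5 days, 481 and 414 without irradiated replicate 1 and 2 at 1 day, and 485 and 517 without sham replicate 1 and 2 at 1 day. By camera with the preset correlation, 9 lists differed between the times. The effect on mitotic genes lay higher at 5 days by a median of 0.35, on DNA replication genes by 0.26, on histone genes by 0.15 and on hypoxia and glycolysis genes by 0.078. The median difference was -0.25 for lysosome genes, -0.16 for p53 targets, -0.13 for metalloproteinases, -0.13 for collagens and -0.16 for cholesterol synthesis. None of the 9 passed with an estimated correlation (adjusted p between 0.259 and 0.729 with an estimated correlation). Without sham replicate 2 at 5 days, 1540 genes passed (4935 at an unadjusted p under 0.05).

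Across genes, which are not independent replicates, the irradiation effects at 1 and 5 days had a Pearson r of 0.282 and a Spearman rho of 0.212 over 18372 genes. The 2 effects share no array. Without sham replicate 1 at 5 days r was 0.0649, without irradiated replicate 1 at 5 days 0.133, and without sham replicate 2 at 1 day 0.121. Of the 128 genes lower at 1 day in the fit of 4 arrays, such as MCM4 and PFKFB4, 107 lay below 0 at 5 days (median log2 change -0.47 at 1 day and -0.12 at 5 days). Of the 37 higher genes, such as MMP3 and CDKN1A, 10 lay above 0 at 5 days (median 0.49 and -0.11). The median over all genes at 5 days was -0.025. Both sets thus lay below 0 by nearly the same amount at 5 days. The 107 of 128 are therefore not separated from a shift common to both sets.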

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

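The tests of scaling, of dividing cells and of RNA quality below, the rule that gave each cell cycle list its own test, the comparison of these lists with lists not called and the score of the 200 genes were chosen after the results were seen.

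The irradiation effect differed between 5 days and 1 day for 9 gene lists (camera, preset correlation). All 9 calls were lost with an estimated correlation (adjusted p between 0.259 and 0.729 with an estimated correlation). The median differences, 5 days minus 1 day on the log2 scale, were 0.348 for mitotic genes, 0.258 for DNA replication genes, 0.152 for replication-dependent histone genes and 0.0778 for hypoxia and glycolysis genes. They were -0.252 for lysosome and autophagy genes, -0.158 for cholesterol synthesis, -0.155 for p53 targets, -0.132 for matrix metalloproteinases and -0.127 for collagens. Adjusted over the list alone, the difference passed for MMP3 (-1.34), MMP14 (-0.881), MMP1 (-0.671), MMP2 (-0.573) and MMP19 (-0.318). It passed for the lysosomal genes NPC1 (-0.615), NEU1 (-0.614), HEXA (-0.529), CTSK (-0.524), CTSD (-0.52), CTSL (-0.42), GLB1 (-0.41), WIPI1 (-0.385) and NPC2 (-0.332). It also passed for GDF15 (-0.659) and CDKN1A (-0.593) among p53 targets, for TFPI2 (-0.858), TNC (-0.553) and MFAP5 (0.48) among matrix genes, for AKR1B10 (-0.438) and CRYAB (-0.648), and for KDR (-0.766) and SRGN (0.614) among markers of other cell types. Over all 18372 genes none of these differences passed.

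The 2 sham arrays at 5 days differed by over 1 log2 unit for 544 genes, each of them lower in replicate 1, VPS13C, ROCK2 and DST among them. Scaling does not account for it, since the SD of the pair was 0.251 after median subtraction against 0.119 for the widest other pair, and neither does noise at low signal, since it was 0.29 among genes with signals of at least 8, against 0.123. A different proportion of dividing cells would shift replication and mitotic genes together. The replication list lay 0.0648 from the median of all genes in this difference, with the mitotic list on the other side (-0.172). The lists did not move together, which argues against dividing cells as the account of differences of over 1 log2 unit. Members of the mitotic list spread widely (SD 0.632), so its median says little of single members. RNA quality or amplification stays open as a candidate explanation: the same genes separated the replicates of other groups at an absolute r of 0.616, 0.417 and, at the weakest, 0.131. No other biological explanation was tested, and the labels name no difference between the 2 arrays.

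The 200 genes lowest in sham replicate 1 at 5 days had a mean of 0.239 higher in irradiated than in sham cells at 1 day. The gap between the 2 sham arrays at 1 day was larger, at 0.379, a ratio of 0.63. Array-to-array variation along these genes may therefore account for the difference. An effect of irradiation on these genes stays open as well, untested apart from that variation.

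DNA replication and mitotic genes lay lower in irradiated cells at 1 day. The mean score of the replication list differed between irradiated and sham arrays by 11.6 times the larger gap within the pairs at 1 day, and that of the mitotic list by 2.56 times. A bound of 3 was set for this ratio, but endothelial markers, a list not called, reached 14.2, so a gap from 2 arrays is too loose a measure of noise to exclude it. Against the largest gap of any pair the ratios were 2.13 and 0.596. With an estimated correlation both lists had adjusted p = 0.256 by camera. That test also has fewer degrees of freedom than the preset one, so it does not decide on shared noise. Secreted factors at 1 day, with an estimated correlation of 0.00409, below the preset 0.01, likewise moved from adjusted p = 0.0103 to 0.256. Replicate noise shared by the members and an effect of irradiation, such as fewer cycling cells, cannot be told apart for either list on 2 arrays per group.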

How the results depend on the processing

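Array weights, all probe sets, signals of at least 8, the crossed pairing, the row with the highest mean as an alternative, the 4 arrays with an estimated correlation and leaving out arrays of the other recovery time were chosen after the data were seen. At 1 day 1 gene passed in the fit of 8 arrays. The count was 14 with array medians subtracted, 165 in the 4 arrays alone, 483 with array weights (158 of them among the 165) and 0 with all probe sets tested, a setting that changes the number of tests, the averaging of probe sets and the moderation at once. It was 0 with a variance trend. Centring gives this trend the mean of the irradiated arrays in place of signal level, so it is not a sound check of MMP3. Leaving out 1 array gave 0 to 118 genes: 118 without sham replicate 1 or 2 at 5 days, and 0 without any other array. The adjusted p of MMP3 at 1 day ran from 1.39e-04 (array weights) to 0.969 (variance trend), with 8 of 16 alternatives under the threshold, and that of MMP1 from 0.00274 to 1. For the other counts, leave-one-out gave 0 to 3795 genes at 5 days and 0 to 1540 for the difference between times. The highest counts came without sham replicate 2 at 5 days, and 0 genes passed without any other array. Without replicate 2, sham replicate 1 is the only sham reference at 5 days. Across genes, irradiated replicates 1 and 2 at 5 days had r of 0.809 and 0.608 with sham replicate 2. With sham replicate 1 these were -0.809 and -0.608. Both irradiated arrays thus lay on the side of sham replicate 2, and further from replicate 1. Why the 2 sham arrays differ was not settled.

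Of 10 lists at 1 day, 0 passed with an estimated correlation, with 8 or 4 arrays, and 9 to 11 lists passed with 1 array left out. With fry 4 lists passed, 3 of the 10 and dermal fibroblast identity genes. Of 6 lists at 5 days, 0 passed with an estimated correlation with 8 or 4 arrays, 2 among signals of at least 8, 3 with fry (1 of the 6), and 2 to 7 with 1 array left out. The correlation between the times ran from 0.0649 to 0.374 with 1 array left out.

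With the replicate block 0 genes passed at 1 day, and the number at 5 days with an unadjusted p under 0.05 was 705 (119 higher, 586 lower) against 1120 (166 and 954). The other counts of calls and of lists did not move by over 1.5 times. Correlations of replicate differences were -0.616 between irradiated and sham arrays at 5 days and -0.0955 at 1 day, so equal numbers do not mark arrays that vary together. A link under another numbering is not excluded. With the sham numbers at 5 days exchanged, this crossed pairing called 1 gene at 1 day and 0 at 5 days.

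Uncalled MMP and TIMP values changed sign with 1 array left out. At 1 day the ranges were -0.0985 to 0.0575 for MMP7, -0.0571 to 0.145 for MMP8, -0.00672 to 0.123 for MMP9, -0.00748 to 0.0499 for MMP13, -0.0603 to 0.152 for MMP24 and -0.138 to 0.0587 for MMP27. At 5 days they were -0.171 to 0.0156 for MMP3, -0.0661 to 0.102 for MMP7, -0.0858 to 0.0937 for MMP8, -0.0592 to 0.0892 for MMP9, -0.0132 to 0.073 for MMP11 and -0.0287 to 0.065 for MMP12. They were -0.263 to 1.1 for MMP16, -0.102 to 0.108 for MMP24, -0.126 to 0.12 for MMP25, -0.0452 to 0.161 for MMP28 and -0.0132 to 0.027 for TIMP1. MMP25 at 5 days was 0.0242 with array medians subtracted. No other gene named by the rule changed sign in an alternative run. Nor did the genes past the adjustment over a list alone or those of the closing part, which were run after the data were seen. The fibrillar collagens named at 1 day were not run. Signal over background cannot be read from centred values. The filter on the mean and quantile normalization were not run.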

Other observations

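The genes in this part and its tests were chosen after their values were seen. In the fit of the 4 arrays at 1 day, IFNE, an interferon of epithelia, had the largest log2 change among the genes called (1.37, adjusted p = 0.0358), and stood at 0.68 at 5 days without passing (0.058 without irradiated replicate 1 at 5 days, 1.3 without replicate 2). POSTN, which encodes the matrix protein periostin, rose by 1.02 (adjusted p = 0.0284), IL13RA2, a decoy receptor for interleukin 13, by 0.65 (adjusted p = 0.0284) and the matrix gene SPON2 by 0.69 (adjusted p = 0.0277). TAGLN, a marker of contractile cells, fell by 0.88 (adjusted p = 0.015), so POSTN and TAGLN, 2 members of the TGF-beta response list, went opposite ways.

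Genes of serine and thymidylate synthesis and of signalling were among those that fell in the same fit. PHGDH, the first enzyme of serine synthesis, fell by 0.49 (adjusted p = 0.0284) and the thymidylate synthase gene TYMS by 0.47 (adjusted p = 0.0411). BMP4 fell by 0.52 (adjusted p = 0.0277), TLR4, the receptor for bacterial lipopolysaccharide, by 0.55 (adjusted p = 0.0332) and ALDH1A1, a retinaldehyde dehydrogenase, by 0.83 (adjusted p = 0.0338). The microfibril genes MFAP5 and FBN2 fell by 0.48 and 0.45 (adjusted p = 0.0284 and 0.0358), while TNC rose by 0.39 (adjusted p = 0.0358). Of the 15 or 16 alternatives run at 1 day for each gene of these 2 paragraphs, 2 to 4 passed, with adjusted p from 0.00191 (TAGLN) to 1.

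A hypothesis tested was that changes at 1 day persisted at 5 days. For the 37 genes higher at 1 day in the fit of 4 arrays, the median change at 5 days was -0.114. It was -0.185 to -0.0655 with 1 array at 5 days left out, against 0.123 for a quarter-sized effect. These rises were thus not seen at 5 days. For the 128 genes lower at 1 day, the median at 5 days in the direction of 1 day was 0.123, with a range of 0.0561 to 0.204 against bounds of 0.116 and 0.232. Plain medians at 5 days were nearly the same for the higher (-0.114) and the lower genes (-0.123), also without sham replicate 1 at 5 days (-0.0655 and -0.0671). Among genes with signals of at least 8, 9 lay higher and 579 lower at an unadjusted p under 0.05 (limma, 8 arrays). A downward shift common to both sets was not separated from persistence. Partial persistence of the lower genes may hold and cannot be told apart from none with these arrays.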
